A study of Homo sapiens with 18 samples.

How the data were processed

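RNA sequencing measured transcript levels in 18 libraries from 2 human prostate cancer cell lines, LNCaP and PC3. Each line had been transduced with a lentivirus carrying 1 of 3 constructs, RSPO2, CTNNB1 or luciferase (LUC), and 3 libraries were made per line and construct. Per the labels' protocols, the cells grew in serum-supplemented RPMI medium, RNA was taken with a column kit, and an outside provider prepared the libraries. Nothing in the labels says that the 3 libraries of a group come from separate cultures, so every p-value given here measures only the spread between samples.

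The values used were the deposited raw counts, whole numbers of reads per gene and library. Per the submitters' processing notes, the tools behind the deposited files were Trimmomatic, HISAT2, SAMtools, featureCounts and DESeq2, with genome build GRCh38 and no versions. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes that share reads with paralogs, overlapping genes or antisense partners are therefore uncertain, and reads of a construct cannot be told from those of the cell's own copy of the gene. The table has 62754 gene rows, of which 38684 held a read. Repeated gene names, 343 of them, were kept apart by a suffix and took 0.0953% of the reads, and 20393 entries named by an Ensembl identifier took 2.79%. Per the submitters' processing notes and the values, the authors also deposited 3 tables of normalized signal. All 36 of their 36 library columns equalled the raw counts divided by 1 size factor per library, within a relative tolerance of 1e-06, and they served only for that check. The variance-stabilized tables the authors deposited were not used.

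Total counts per library ranged from 8951320 to 17682396. The floor used for a gene without reads was 3 counts, over the group where a group is described and per library otherwise, which per library equals 0.170 to 0.335 CPM. Where a group held 0 reads of a gene, a fold is given as a lower bound against that floor, and where it held 1 to 3 reads, the ratio of the groups is given with an exact 95% interval from the counts. These intervals and floors cover counting error only.

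Differential expression was tested with edgeR 4.0.16, using TMM normalization, the default expression filter on the groups of each fit, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. All adjusted p-values of single genes come from this test unless another tool is named. The 6 comparisons within a line (RSPO2 against LUC, CTNNB1 against LUC and RSPO2 against CTNNB1) were each fitted to the 9 libraries of that line. A fit of all 18 libraries gave the differences between lines in the effect of RSPO2 and of CTNNB1, and the comparison of the LUC libraries of both lines. Standard errors (SE) of log2 fold changes were obtained as the absolute log2 fold change divided by the square root of F. Levels are CPM, counts scaled to 1e6 of the TMM-scaled library size, given as mean ± SD over 3 libraries.

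Before the data were examined, 32 gene lists were written from general knowledge, together with the design, the rule for naming genes and all alternatives except those named as added. Each list with at least 5 tested members was tested by limma's camera (version 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided and adjusted over the lists of a comparison. The test was repeated with an estimated correlation and with fry. Members past the threshold were counted with adjustment over all genes tested and adjusted over the list alone. The immune cell list never reached 5 tested members, the fibroblast list did not in LNCaP, and the endothelial list did not in PC3. Genes were named by a fixed rule: RSPO2 and CTNNB1; the 8 largest rises and 8 largest falls among genes past the threshold with an edgeR mean log2 CPM of at least 1, no overlap between the libraries of both groups and a protein-coding symbol; up to 4 members with the smallest adjusted p of each list described; and a panel of 17 genes of Wnt signalling, androgen response, cell identity and proliferation. The comparison of the LUC libraries names only list members and panel genes. CTNNA1, MSH2, HEXA, TP53 and PTEN were looked at as genes whose state differs between the lines, after the profile of the libraries labelled LNCaP RSPO2 had been seen, with HEXA also named by the rule.

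Gene positions were taken from the GENCODE 29 annotation of GRCh38. Overlaps of calls are given with the overlap of independent lists of the same sizes, and, within a line, with 20 simulations of unchanged groups. In these, all libraries of the line, LUC included, were redrawn around the LUC means, and both comparisons used the same simulated LUC libraries. The fits were tested on simulated counts made from the mean levels of the line's LUC libraries and the real library sizes, with 50 genes changed at each fold in each of 3 runs. Changed genes were drawn only from those above a minimum level in LUC, so the shares called do not hold for genes of low counts. For CTNNB1 against LUC in LNCaP, the simulated changes of 1.5, 2, 4 and 8-fold were called in 66.7%, 89.3%, 98.7% and 100% of cases. In PC3 these shares were 70.7%, 92.0%, 100% and 100%. Of unchanged genes, 0.0783% were called in LNCaP and 0.0712% in PC3.

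The alternatives were RLE and upper-quartile normalization, no expression filter, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, RSPO2 and CTNNB1 left out of the counts, each library left out in turn, only the 6 libraries compared, and all 18 libraries in one fit. Leaving out libraries whose labels or purity are in doubt was added after the data had been seen. Other groupings of the libraries were also fitted, all 10 splits for each comparison of 3 against 3 and 50 drawn splits for each difference between lines. Calculations used R 4.3.3, the package data.table in version 1.17.8, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots matplotlib 3.10.9.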

Results

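RNA sequencing measured transcript levels in 18 libraries of the human prostate cancer lines LNCaP, which comes from a lymph node metastasis and responds to androgens, and PC3, which comes from a bone metastasis and grows without them. Each line carried a lentiviral construct for RSPO2, a secreted R-spondin that strengthens Wnt signalling, for CTNNB1, the gene of β-catenin, which carries canonical Wnt signals into the nucleus, or for luciferase (LUC), the control. Each of the 6 groups held 3 libraries. Total counts ranged from 8951320 in PC3 LUC replicate 3 to 17682396 in PC3 LUC replicate 1. The 50 most abundant genes took 15.7% to 16.2% of the counts in the PC3 LUC libraries and 10.0% to 11.7% in all others. Changes are given as log2 fold changes with their standard error (SE) and the adjusted p of edgeR's quasi-likelihood test, and levels as CPM (counts scaled to 1e6 per library), mean ± SD, n = 3. Intervals and floors cover counting error only. Genes named for the largest changes of a comparison showed no overlap between the libraries of both groups.

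The libraries fell into 4 sets by their whole profile. The first principal component of log2 CPM, with 79.3% of the variance, set the LNCaP CTNNB1 and LNCaP LUC libraries apart from all PC3 libraries and from the 3 libraries labelled LNCaP RSPO2. The second, with 10.7%, put the PC3 RSPO2 and PC3 CTNNB1 libraries at 55.2 to 73.7, the PC3 LUC libraries at -72.9 to -72.0 and the libraries labelled LNCaP RSPO2 at -52.9 to -49.4. Across genes, the libraries labelled LNCaP RSPO2 correlated with PC3 LUC at a mean r of 0.961 and with LNCaP LUC at 0.698, while libraries of the same group correlated at 0.986 to 0.992. Genes are not independent replicates, so these correlations describe the profiles and carry no test.

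**Figure D1:**
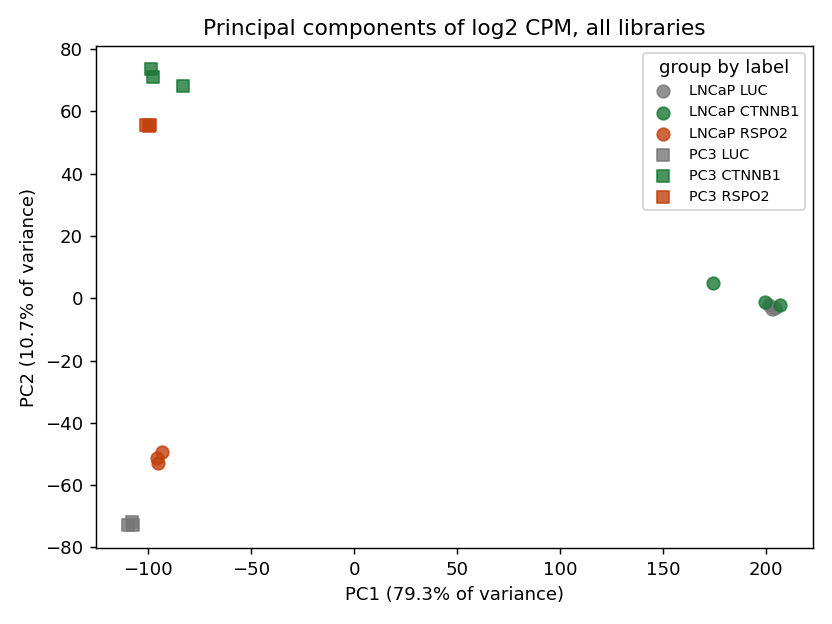
First and second principal components of log2 CPM for the 18 libraries, with the share of variance on each axis (79.3% and 10.7%). Circles are libraries labelled LNCaP and squares libraries labelled PC3; colors give the construct. The 3 libraries labelled LNCaP RSPO2 lie on the side of the PC3 libraries, nearest to PC3 LUC.

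The constructs themselves were measured first, since their transcripts check the labels. RSPO2 (GRCh38, chromosome 8, 107899316 to 108083648, minus strand) stood at 1068 ± 18.5 CPM in PC3 RSPO2 and 431 ± 11.5 CPM in the libraries labelled LNCaP RSPO2. In the other 4 groups its mean was 0.253 to 0.586 CPM, from 0 to 8 reads per library. Against LUC it rose by 11.16 in PC3 (SE 0.22, adjusted p = 3.75e-16) and by 10.54 in the libraries labelled LNCaP RSPO2 (SE 0.17, adjusted p = 8.63e-15). CTNNB1 (GRCh38, chromosome 3, 41194741 to 41260096, plus strand) was 624 ± 19.6 CPM in LNCaP CTNNB1 against 321 ± 7.37 in LNCaP LUC, a rise of 0.93 (SE 0.05, adjusted p = 9.39e-07). In PC3 it was 479 ± 6.30 CPM with the CTNNB1 construct, 442 ± 8.65 with RSPO2 and 285 ± 1.86 with LUC, so that it rose against LUC by 0.75 with CTNNB1 (SE 0.04, adjusted p = 1.19e-10) and by 0.62 with RSPO2 (SE 0.04, adjusted p = 1.66e-09). With RSPO2 against CTNNB1 in PC3 it was at -0.13 (SE 0.04, adjusted p = 0.0213), a call lost with no filter (0.0956), without RSPO2 replicate 1 (0.0547) or 2 (0.0845) and without CTNNB1 replicate 2 (0.0713). Reads from a construct and from the cell's own gene cannot be told apart in these counts.

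**Figure D2:**
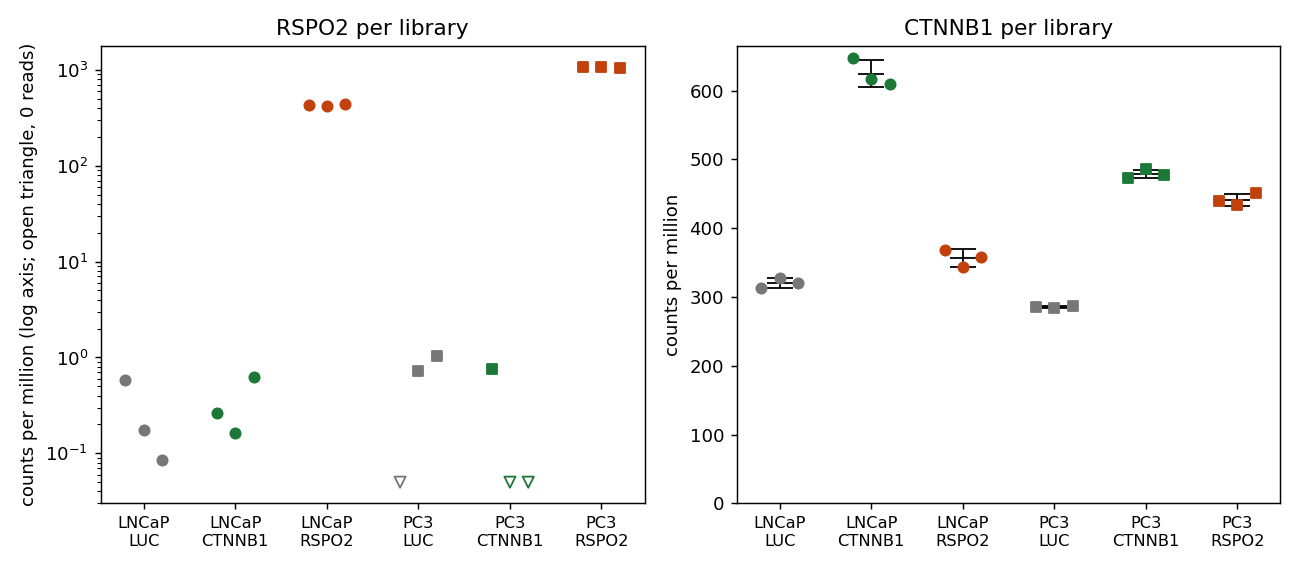
RSPO2 (log axis) and CTNNB1 (linear axis) in CPM for each library of the 6 groups, with group mean and SD for CTNNB1; open triangles mark libraries with 0 RSPO2 reads. RSPO2 was high only in the 2 groups with its construct, and CTNNB1 was 624 CPM in LNCaP CTNNB1 and 479 CPM in PC3 CTNNB1. In PC3, CTNNB1 was also higher with RSPO2 than with LUC, at a level close to that with its own construct.

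The libraries labelled LNCaP RSPO2 did not have the levels of the other LNCaP libraries at genes that set the lines apart. CTNNA1 (α-catenin, GRCh38, chromosome 5, 138610967 to 138935034), which PC3 lacks through a deletion, was 1.94 ± 0.384 CPM in them, 386 ± 7.40 in LNCaP LUC and 1.45 ± 0.441 in PC3 LUC. MSH2 (GRCh38, chromosome 2, 47402969 to 47663146), the mismatch repair gene that LNCaP has lost, was 141 ± 5.39 CPM in them, 19.2 ± 0.778 in LNCaP LUC and 122 ± 6.98 in PC3 LUC. HEXA, a lysosomal hexosaminidase subunit (GRCh38, chromosome 15, 72340919 to 72376476), had 0 reads in them and in PC3 RSPO2, and 33.6 ± 3.03 CPM in LNCaP LUC. TP53 was 8.02 ± 1.25 CPM in them, 241 ± 7.87 in LNCaP LUC and 6.04 ± 0.815 in PC3 LUC. These 4 genes were chosen after the profile had been seen, HEXA also by the naming rule. Every direction below that rests on the libraries labelled LNCaP RSPO2 compares a PC3-type profile with a LNCaP-type one.

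**Figure D3:**
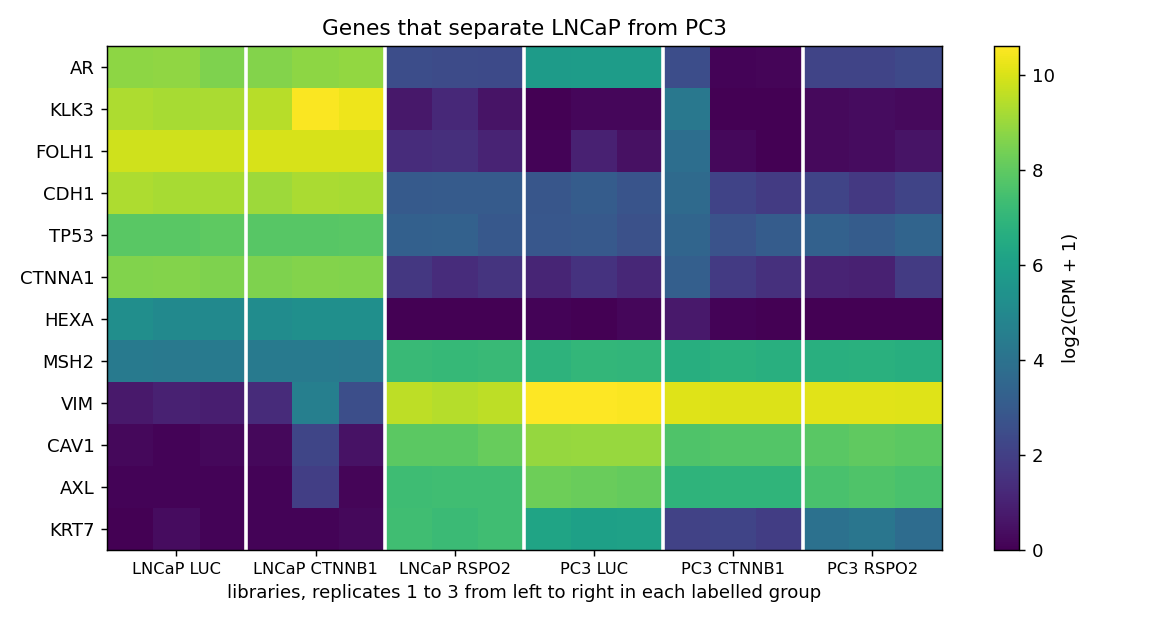
Heat map of log2(CPM + 1) for 12 genes (lines) in the 18 libraries (columns, grouped by label). The libraries labelled LNCaP RSPO2 show the pattern of the PC3 libraries, with CTNNA1 at 1.94 CPM against 386 CPM in LNCaP LUC.

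CTNNB1 against LUC in LNCaP asks what more β-catenin transcript changes in androgen-responsive cells. Of 36 androgen response genes 10 rose, and the call of the list ended with an estimated correlation (0.594). Among the 10 were ADAMTS1, a secreted protease, by 0.65 (SE 0.05, adjusted p = 2.15e-05), SLC45A3, a prostate transporter, by 0.64 (SE 0.06, adjusted p = 0.000168), PMEPA1, an inhibitor of TGF-β signalling, by 0.49 (SE 0.05, adjusted p = 0.000198), and NKX3-1, a prostate homeobox factor, by 0.49 (SE 0.06, adjusted p = 0.00049). SEMA3E, a guidance ligand, fell by 2.71 from 115 ± 6.95 CPM (SE 0.11, adjusted p = 3.24e-08). PHLDA1, an immediate early gene, rose 2.82-fold, from 19.7 ± 1.15 to 56.7 ± 8.44 CPM (SE of the log2 fold change 0.09, adjusted p = 1.38e-06). Of 17361 genes tested, 451 passed the threshold, 200 higher and 251 lower, and 76 of them changed over 2-fold. The groups did not overlap at 21.1% of the genes, where chance gives 10%.

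Of the 36 tested androgen response genes, 10 rose and 0 fell, or 19 and 0 adjusted over the list alone, and 7 rose without the doubted libraries (camera adjusted p = 1.2e-09; adjusted p = 0.594 with an estimated correlation). The LNCaP-type luminal markers gave 7 rises and 0 falls among 14, or 9 and 1 adjusted over the list alone, and 4 rises without the doubted libraries (adjusted p = 4.75e-05; 0.594 with an estimated correlation, also a p). The androgen receptor itself (AR) changed by 0.01 (adjusted p = 0.975). KLK3, which codes for prostate-specific antigen (GRCh38, chromosome 19, 50854915 to 50860764), rose by 0.89 (SE 0.18, adjusted p = 0.0198), from 611 ± 17.3 to 1161 ± 402 CPM, with 8134, 17988 and 14370 reads in the CTNNB1 libraries and 6786 to 7473 in LUC. It stayed at 0.70 to 0.91 but lost its call without CTNNB1 replicate 3 (0.0696) or LUC replicates 1, 2 or 3 (0.089, 0.0937 and 0.0742), with DESeq2 (0.125) and without the doubted libraries (0.0892). TMPRSS2 was at 0.39 (adjusted p = 0.324), and it passed with no filter (0.39, adjusted p = 1.55e-06) and without CTNNB1 replicate 1 (0.65, adjusted p = 6.46e-06).

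Of 26 feedback and target genes of Wnt/β-catenin signalling, 0 rose and 1 fell, or 3 and 1 adjusted over the list alone (adjusted p = 0.134; 0.623 with an estimated correlation, also a p), and camera called the list, upward, only without CTNNB1 replicate 1 (0.0158). The member that fell was MYC, a growth regulator, by 0.35 (SE 0.05, adjusted p = 0.00134). AXIN2, a direct feedback target, was at 0.35 (SE 0.23, adjusted p = 0.512). LGR5 did not pass at 3.35, with 0, 12 and 2 reads in the CTNNB1 libraries. It passed with no filter (adjusted p = 0.0113) and at 3.90 without CTNNB1 replicate 1 (adjusted p = 0.0412). Among Wnt ligands 1 of 9 fell, WNT10B, by 0.80 (SE 0.14, adjusted p = 0.00856), or 2 adjusted over the list alone (list adjusted p = 0.225; 0.641 with an estimated correlation, also a p). None of the 17 tested R-spondin and Wnt receptor genes passed the threshold, also adjusted over the list alone (list adjusted p = 0.232; 0.594 with an estimated correlation, also a p). ATF4 and amino acid stress genes gave 0 rises and 2 falls among 30, the transporters SLC7A5 by -0.52 (SE 0.06, adjusted p = 0.000723) and SLC7A1 by -0.44 (SE 0.07, adjusted p = 0.00518), with the same counts adjusted over the list alone (adjusted p = 0.00376; 0.594 with an estimated correlation, also a p).

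The 5 largest rises were genes with 16.6 ± 1.95 CPM (PDE3A) to 75.4 ± 3.38 CPM (CDH2) in PC3 CTNNB1, and within the LNCaP CTNNB1 group each had the most reads in replicate 2. HLA-A, an antigen-presenting molecule whose reads can be shared with its paralogs (GRCh38, chromosome 6, 29941260 to 29945884), had 2, 12 and 4 reads in the CTNNB1 libraries and 0 in the LUC libraries, at least 6.05-fold higher. The ratio to LUC was 30.3 (95% interval 5.03 to 1235) for HMGA2, a chromatin architecture protein, 20.7 (5.37 to 176.5) for CDH2, which codes for N-cadherin, 12.6 (3.14 to 110) for CLIP4 and 14.1 (2.15 to 597) for PDE3A. APBA2 rose by 1.75 (SE 0.42, adjusted p = 0.0437) and CD302 by 1.49 (SE 0.36, adjusted p = 0.0444). VIM, the mesenchymal filament vimentin, had 17, 275 and 54 reads in the CTNNB1 libraries and 8, 11 and 10 in the LUC libraries, which gave 3.52 (SE 0.90, adjusted p = 0.0592), and it passed at 1.90 without CTNNB1 replicate 2 (adjusted p = 0.0299), without replicate 1 (0.00108) or replicate 3 (0.0488), with DESeq2 (0.00397) and with no filter (9.57e-66), but not without the doubted libraries (0.0892). Mesenchymal genes gave 1 rise and 2 falls among 25, or 11 and 2 adjusted over the list alone. Their median was 0.55 (camera adjusted p = 0.000707, or 0.594 with an estimated correlation). They gave 3 rises and 1 fall among 26 without CTNNB1 replicate 2, and 1 and 1 among 18 without the doubted libraries. With only the 6 libraries compared, 0 of 18 rose and 1 fell. PC3-type markers gave 1 rise and 1 fall among 15, or 7 and 1 adjusted over the list alone (adjusted p = 0.0226; 0.594 with an estimated correlation, also a p), and this call ended without CTNNB1 replicate 2 (0.113) or without LUC replicate 1. In the other direction, the ratio was 0.0961 (0.0109 to 0.393) for CNTNAP3B, a neuronal adhesion gene with close paralogs, and CDH3 (P-cadherin) fell by 2.81 (SE 0.38, adjusted p = 0.00124).

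The number of calls moved with single libraries, to 1120 without CTNNB1 replicate 1 and 247 without replicate 3, and to 175, 227 and 271 without LUC replicates 1, 2 and 3, while 265 genes passed without CTNNB1 replicate 2 and the libraries labelled LNCaP RSPO2. HLA-A, HMGA2, CDH2, CLIP4, PDE3A, APBA2 and CD302 lost their calls without LUC replicate 1 and without LUC replicate 3, all of these but CDH2 without LUC replicate 2, HLA-A, HMGA2, CDH2, PDE3A and APBA2 without CTNNB1 replicate 3, HMGA2, PDE3A, APBA2 and CD302 without CTNNB1 replicate 2, and CD302 without CTNNB1 replicate 1, at adjusted p between 0.0519 and 0.183. Without CTNNB1 replicate 2 the log2 fold changes stayed at 3.63 for HMGA2, 3.19 for PDE3A, 1.30 for APBA2 and 1.39 for CD302, so these lost calls do not show that replicate 2 alone made the rises. With the replicate number as a block, HLA-A (0.0639), CDH2 (0.0521), PDE3A (0.0778), APBA2 (0.0909) and CD302 (0.0885) also lost their calls, and so did PDE3A with DESeq2 (0.0642). CNTNAP3B lost its call without CTNNB1 replicates 2 and 3 (0.0529 and 0.0858) and LUC replicates 2 and 3 (0.109 and 0.0845). Over normalization, filter, block and left-out libraries, the adjusted p of the androgen response list stayed between 2.2e-15 and 2.97e-06, that of the luminal list between 1.29e-06 and 0.00144, that of the ATF4 list between 0.000291 and 0.547, and that of the Wnt target list between 0.0158 and 0.407.

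RSPO2 against LUC in LNCaP asks what a secreted Wnt activator changes in the same cells, but here the libraries labelled LNCaP RSPO2 carried the PC3-type profile described above. Among luminal genes, FOLH1, prostate-specific membrane antigen, was at -9.25 (SE 0.10, adjusted p = 3.08e-16), NKX3-1 at -7.03 (SE 0.09, adjusted p = 1.15e-15), AR (GRCh38, chromosome X, 67544032 to 67730619) at -6.54 (SE 0.11, adjusted p = 1.4e-14) and the epithelial cadherin CDH1 at -6.35 (SE 0.08, adjusted p = 1.15e-15). The urokinase PLAU rose by 12.02 (SE 0.25, adjusted p = 4.77e-14), the keratin KRT7 by 10.34 (SE 0.18, adjusted p = 1.55e-14), VIM by 9.79 (SE 0.58, adjusted p = 1.68e-09) and the mesenchymal factor ZEB1 by 4.63 (SE 0.10, adjusted p = 8.06e-14). Of 17361 genes tested, 14262 passed the threshold, 7116 higher and 7146 lower, and 8285 of them changed over 2-fold. The groups did not overlap at 84.3% of the genes, where chance gives 10%.

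Among genes with no reads in one group, EDIL3 was at least 1041-fold, SCARA5 at least 1018-fold, KRT75 at least 861-fold and TFPI2 at least 854-fold higher in the libraries labelled LNCaP RSPO2. In the other direction, IRX4 was at least 613-fold, PAX1 at least 579-fold, VCX, which shares reads with close paralogs, at least 479-fold and RAB25 at least 409-fold lower. All 14 tested LNCaP-type luminal markers fell (adjusted p = 4.5e-07; 0.255 with an estimated correlation, also a p), and all 15 PC3-type markers rose (adjusted p = 1.97e-05; 0.315 with an estimated correlation, also a p). Of 36 androgen response genes 31 fell and 5 rose (adjusted p = 4.5e-07; 0.318 with an estimated correlation). Mesenchymal genes gave 21 rises and 2 falls among 25, with COL6A2 at 4.02 (SE 0.07) and FBN1 at 6.46 (SE 0.13) (adjusted p = 5.25e-05; 0.330 with an estimated correlation). Epithelial genes gave 4 rises and 26 falls among 32, with the epithelial regulator GRHL2 at -8.62 (SE 0.15) (adjusted p = 4.76e-06; 0.163 with an estimated correlation). DNA replication genes of the G1/S transition gave 2 rises and 36 falls among 39, with DHFR at -2.86 (SE 0.07) and MCM2 at -1.97 (SE 0.06) (adjusted p = 2.73e-07; 0.315 with an estimated correlation). Interferon response genes gave 33 rises and 4 falls among 40, with PARP14 at 3.56 (SE 0.13) and ISG15 at 2.40 (SE 0.10) (adjusted p = 0.000112; 0.556 with an estimated correlation). The counts of these lists were the same adjusted over the list alone, and their adjusted p stayed between 1.05e-07 and 0.000147 over normalization, filter, block and left-out libraries.

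Wnt/β-catenin target genes went both ways, with 15 rises and 11 falls among 26, the same adjusted over the list alone (adjusted p = 0.592; 0.828 with an estimated correlation). CD44 rose by 10.49 (SE 0.33) and SOX9 by 5.38 (SE 0.18), while CAB39L fell by 2.49 (SE 0.08, adjusted p = 1.93e-12) and the Wnt receptor ligases RNF43 and ZNRF3 fell by 3.19 and 1.18. AXIN2 rose by 0.62 (adjusted p = 0.0227) and lost its call without RSPO2 replicate 3 (0.107) or LUC replicate 3 (0.109). Against the LNCaP CTNNB1 libraries, the libraries labelled LNCaP RSPO2 gave 14276 calls among 17361 genes, 7193 higher and 7083 lower, with 83.2% of genes not overlapping where chance gives 10%. PDPN was at least 349-fold and GIPC3 at least 223-fold higher, the ratio for KRT75 was 2560 (95% interval 459 to 101160), the hair keratin KRT81 rose by 10.54 (SE 0.11, adjusted p = 2.99e-16), and VCX was at least 708-fold, IRX4 at least 528-fold and HPN at least 400-fold lower. In that comparison all 14 luminal markers fell (adjusted p = 2.29e-07; 0.252 with an estimated correlation, also a p), all 15 PC3-type markers rose (adjusted p = 3.73e-05; 0.306 with an estimated correlation, also a p), and androgen response genes gave 3 rises and 32 falls among 36 (adjusted p = 9.88e-08; 0.306 with an estimated correlation), all with the same counts adjusted over the list alone.

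RSPO2 against LUC in PC3 asks what the secreted Wnt activator changes in androgen-independent cells. Among interferon response genes, HERC6 rose by 4.46 (SE 0.22, adjusted p = 1.89e-11), the RNA sensor gene OAS1 by 3.01 (SE 0.15, adjusted p = 2.07e-11) and the ISG15-conjugating enzyme UBE2L6 by 2.53 (SE 0.11, adjusted p = 3.46e-12). LGR5, a receptor for R-spondins and a Wnt target (GRCh38, chromosome 12, 71439770 to 71586310), rose by 3.31, from 16.7 ± 1.15 to 166 ± 14.1 CPM (SE 0.08, adjusted p = 4.79e-15). The libraries labelled LNCaP RSPO2, which also carry RSPO2, held 51, 31 and 27 LGR5 reads, against 122 to 250 in PC3 LUC. Fibronectin (FN1) was at -3.48 (SE 0.06, adjusted p = 5.43e-17) and CA9, a hypoxia-induced carbonic anhydrase, at -5.53 (SE 0.14, adjusted p = 5.02e-15). AXIN2 (GRCh38, chromosome 17, 65528563 to 65561647) fell 2.82-fold, from 7.39 ± 1.40 to 2.62 ± 1.21 CPM (SE of the log2 fold change 0.28, adjusted p = 0.000208). Of 16214 genes tested, 10504 passed the threshold, 5243 higher and 5261 lower, and 3225 of them changed over 2-fold. The groups did not overlap at 69.0% of the genes, where chance gives 10%.

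ADD2, a membrane skeleton protein, was at least 255-fold, the carboxypeptidase CPB1 at least 111-fold and PYGO1, a nuclear partner of β-catenin, at least 92.0-fold higher in PC3 RSPO2. The hematopoietic transcription factor GATA2 (GRCh38, chromosome 3, 128479427 to 128493185) reached 37.0 ± 3.30 CPM, a ratio to LUC of 1154 (95% interval 207 to 45638). TTLL10, a tubulin-modifying enzyme, was at least 297-fold lower, from 30.0 ± 1.11 CPM in LUC, and the ratio for CLMN was 0.00297 (0.000612 to 0.00871). The receptor kinase ALK fell by 7.74 (SE 0.21, adjusted p = 1.33e-14), LIMCH1 by 7.40 (SE 0.68, adjusted p = 6.63e-08), ABTB3 by 7.39 (SE 0.25, adjusted p = 1.75e-13) and the protease ADAM12 by 7.29 (SE 0.19, adjusted p = 6.06e-15). AR fell by 3.94, from 56.5 ± 0.361 to 3.68 ± 0.320 CPM (SE 0.36, adjusted p = 6.7e-08), and the mesenchymal factor SNAI2 fell by 2.57 (SE 0.21, adjusted p = 1.88e-08). Reads in the libraries labelled LNCaP RSPO2, which also carry RSPO2, were 54, 43 and 44 for AR against 32 to 41 in PC3 RSPO2. For GATA2 they were 10, 6 and 6 against 339 to 399, and for ADD2 3, 1 and 3 against 221 to 253.

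Interferon response genes gave 41 rises and 1 fall among 44, or 42 and 1 adjusted over the list alone, with a median of 2.47 (adjusted p = 1.31e-11; 0.452 with an estimated correlation, also a p). Hypoxia and glycolysis genes gave 2 rises and 29 falls among 34, or 2 and 31 adjusted over the list alone, with the glycolytic enzymes PFKP (adjusted p = 6.19e-14) and HK2 at -1.46 (SE 0.05) (adjusted p = 1.94e-08; 0.177 with an estimated correlation, also a p). Genes of the unfolded protein response gave 1 rise and 22 falls among 25, with the chaperones PDIA4 at -1.33 (SE 0.05) and HSPA5 at -1.10 (SE 0.06) (adjusted p = 8.61e-07; 0.357 with an estimated correlation, also a p). Cholesterol synthesis genes gave 2 rises and 21 falls among 24, with STARD4 at -1.81 (SE 0.06) and PCSK9 at -3.48 (SE 0.15) (adjusted p = 2.22e-06; 0.177 with an estimated correlation, also a p). Mesenchymal genes gave 3 rises and 20 falls among 27, with the protease MMP14 at -3.00 (SE 0.05) and the integrin ITGA5 at -3.19 (SE 0.08) (adjusted p = 2.31e-05; 0.177 with an estimated correlation, also a p). PC3-type markers gave 0 rises and 13 falls among 14, with PLAU at -2.44 (SE 0.06) and TM4SF1 at -1.68 (SE 0.04) (adjusted p = 2.22e-06; 0.177 with an estimated correlation, also a p). G1/S genes gave 24 rises and 4 falls among 39, with UNG at 1.22 (SE 0.07) and POLA1 at 1.67 (SE 0.09) (adjusted p = 0.000563; 0.492 with an estimated correlation, also a p). Epithelial genes gave 4 rises and 14 falls among 21, with ELF3 at -4.70 (SE 0.15) (adjusted p = 0.00774; 0.177 with an estimated correlation), and basal genes 2 rises and 11 falls among 16, with the laminin LAMB3 at -3.73 (SE 0.08) (adjusted p = 0.00994; 0.236 with an estimated correlation). Where no other count is given, counts adjusted over the list alone were the same. In the libraries labelled LNCaP RSPO2 against PC3 LUC, interferon genes gave 9 rises and 6 falls among 44 (camera adjusted p = 0.493). Hypoxia genes gave 2 rises and 17 falls among 35 there (camera adjusted p = 0.00416). Mesenchymal genes gave 2 and 17 among 28 (0.00623) and epithelial genes 4 and 17 among 32 (0.0302). Cholesterol synthesis, unfolded protein response and G1/S genes also went as with PC3 RSPO2. PC3-type markers (4 and 9 among 15) and basal genes (4 and 7 among 18) did not pass (0.493 each), nor did any of these lists with an estimated correlation. Both comparisons share the PC3 LUC libraries.

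Of 19 tested Wnt/β-catenin target genes, 7 rose and 10 fell, the same adjusted over the list alone (adjusted p = 0.873; 0.910 with an estimated correlation). Beside LGR5, the Wnt antagonist DKK1 rose by 2.01 (SE 0.05, adjusted p = 5.7e-15), and the receptors EPHB2 and TNFRSF19 fell by 5.08 (SE 0.15, adjusted p = 2.23e-14) and 3.77 (SE 0.35, adjusted p = 8.19e-08). TCF7 fell by 0.79 (SE 0.17, adjusted p = 0.000826), MYC by 0.26 (SE 0.05, adjusted p = 0.00026) and the cyclin CCND1 by 0.14 (SE 0.04, adjusted p = 0.0087). ZNRF3 was at 0.34 (SE 0.12, adjusted p = 0.0178) and lost its call without RSPO2 replicate 1 (0.0846) or LUC replicate 1 (0.132). Wnt ligands gave 1 rise and 7 falls among 8, the same adjusted over the list alone (adjusted p = 0.0134; 0.177 with an estimated correlation, also a p): WNT7A fell by 4.83 (SE 0.11, adjusted p = 9.16e-16) and WNT7B by 2.87 (SE 0.08), while WNT5B rose by 4.51 (SE 0.42). Over normalization, filter, block and left-out libraries, the adjusted p of the called lists described for this comparison stayed between 1.4e-13 and 0.0152, and that of the Wnt target list between 0.74 and 0.995.

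CTNNB1 against LUC in PC3 asks what the CTNNB1 construct changes in the same cells. CTNNB1 transcript was also higher than in LUC in PC3 RSPO2, which lacks that construct, so the comparison does not isolate more β-catenin transcript. Among interferon response genes, XAF1 rose (adjusted p = 6.52e-12), OAS1 by 3.18 (SE 0.15) and UBE2L6 by 2.52 (SE 0.11, adjusted p = 3.18e-12). The serine synthesis enzyme PSAT1 was at 1.78 (SE 0.07, adjusted p = 1.49e-12), the transporter SLC7A5 at 1.37 (SE 0.06) and the mitochondrial folate enzyme MTHFD2 at 1.24 (SE 0.06). MMP14 was at -3.17 (SE 0.05, adjusted p = 3.37e-17), and the collagens COL6A1 and COL6A2 were at -3.14 (SE 0.06) and -2.94 (SE 0.05). The transcription factor MYB (GRCh38, chromosome 6, 135181315 to 135219173) rose by 9.41, from a mean of 0.108 to 94.9 ± 3.35 CPM (SE 0.18, adjusted p = 2.15e-16). AXIN2 fell by 3.45, from 7.39 ± 1.40 to 0.643 ± 0.280 CPM (SE 0.35, adjusted p = 1.85e-07). Of 16214 genes tested, 10634 passed the threshold, 5412 higher and 5222 lower, and 3504 of them changed over 2-fold. The groups did not overlap at 68.0% of the genes, where chance gives 10%.

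ADD2 was at least 184-fold and PYGO1 at least 96.1-fold higher in PC3 CTNNB1, and the ratio to LUC was 805 for TUB (95% interval 144 to 31815). AFF2 was at least 377-fold lower, from 36.5 ± 5.69 CPM in LUC, TTLL10 at least 323-fold and the focal adhesion protein TNS1 at least 140-fold. The ratio was 0.000709 (1.79e-05 to 0.00396) for CNTN1 and 0.000876 (0.000181 to 0.00256) for the collagen COL5A1, and ADRA1B had 0 reads against 308 in LUC. The mucin MUC5B fell by 9.59, from 733 ± 206 to 0.922 ± 0.354 CPM (SE 0.28, adjusted p = 2.41e-14), and ALK was at -9.45 (SE 0.25, adjusted p = 7.51e-15). AR fell by 5.13 (SE 0.41, adjusted p = 1.1e-08), with 49, 1 and 1 reads in the CTNNB1 libraries against 854, 466 and 441 in LUC. The 49 reads were in PC3 CTNNB1 replicate 1, which also held 192 reads of KLK3 where the other 2 held 0, and without it AR was at -9.06 (adjusted p = 4.47e-15). SNAI2 fell by 5.57 (SE 0.31, adjusted p = 8.06e-11).

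Interferon response genes gave 43 rises and 1 fall among 44, with a median of 2.55 (adjusted p = 3.91e-12; 0.330 with an estimated correlation, also a p). ATF4 and amino acid stress genes gave 27 rises and 1 fall among 30, with a median of 0.96 (adjusted p = 5.37e-07; 0.297 with an estimated correlation, also a p). Cholesterol synthesis genes gave 0 rises and 23 falls among 24, with STARD4 at -2.04 (SE 0.06, adjusted p = 4.03e-14) and DHCR24 at -1.61 (SE 0.05) (list adjusted p = 2.1e-08; 0.152 with an estimated correlation, also a p). All 14 PC3-type markers fell, with PLAU at -3.46 (SE 0.06) and KRT7 at -4.39 (SE 0.13) (adjusted p = 8.29e-08; 0.152 with an estimated correlation, also a p). Mesenchymal genes gave 3 rises and 21 falls among 27 (adjusted p = 1.3e-06; 0.152 with an estimated correlation, also a p). Hypoxia genes gave 5 rises and 26 falls among 34, with CA9 at -8.24 (SE 0.19, adjusted p = 1.13e-15) and GAPDH at -0.98 (SE 0.04) (list adjusted p = 3.82e-05; 0.264 with an estimated correlation, also a p). Basal genes gave 1 rise and 13 falls among 16, with LAMB3 at -4.77 (SE 0.09) and the integrin ITGB4 at -2.77 (SE 0.08) (adjusted p = 0.000245; 0.152 with an estimated correlation, also a p). Genes of the MYC and ribosome biogenesis list gave 20 rises and 4 falls among 38, or 20 and 3 adjusted over the list alone, with UTP20 at 0.97 (SE 0.07) and TCOF1 at 0.46 (SE 0.05) (adjusted p = 0.0294; 0.471 with an estimated correlation, also a p). For all other lists of this paragraph the counts adjusted over the list alone were the same.

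Of 19 Wnt/β-catenin target genes, 8 rose and 10 fell, the same adjusted over the list alone (adjusted p = 0.828). LGR5 rose by 1.57 (SE 0.09, adjusted p = 1.63e-10), DKK1 by 1.07 (SE 0.05, adjusted p = 1.08e-11) and MYC by 0.41 (SE 0.05, adjusted p = 1.13e-06), while EPHB2 fell by 6.14 (SE 0.16, adjusted p = 7.83e-15) and CCND1 by 0.76 (SE 0.04, adjusted p = 1.14e-10). ZNRF3 was at 0.13 (adjusted p = 0.338). Wnt ligands gave 1 rise and 6 falls among 8, the same adjusted over the list alone (adjusted p = 0.0294; 0.203 with an estimated correlation, also a p), with WNT7B at -6.07 (SE 0.11) and WNT7A at -7.16 (SE 0.14), and WNT5B at 6.69 (SE 0.33). Over normalization, filter, block and left-out libraries, the adjusted p of the called lists described for this comparison stayed between 5.09e-14 and 0.0396, and that of the Wnt target list between 0.703 and 0.886.

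**Figure D4:**
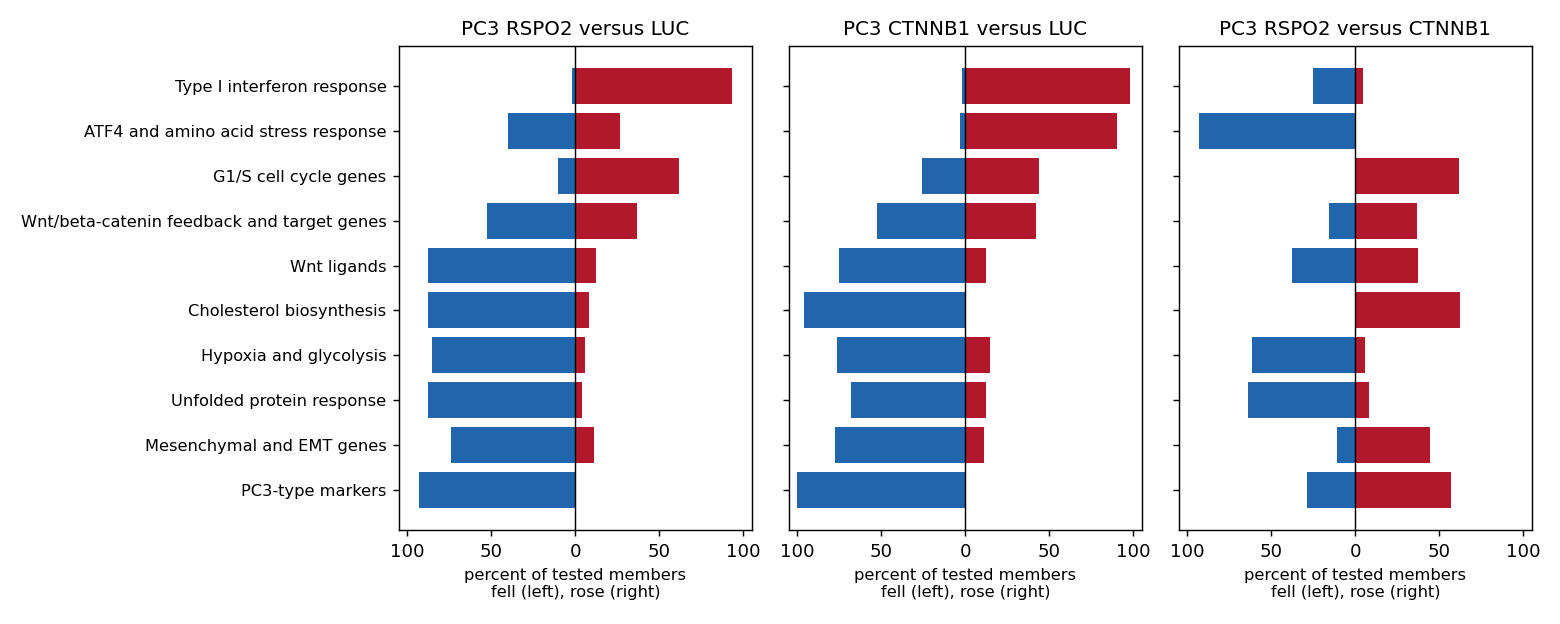
Percent of the tested members of 10 gene lists that fell (left, blue) or rose (right, red) past an adjusted p of 0.05 in 3 comparisons of PC3 libraries. Interferon genes rose and PC3-type markers fell with both constructs against LUC, while ATF4 and amino acid stress genes rose with CTNNB1 (27 of 30).

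Many genes changed in the same direction with both constructs in PC3. Of the 16214 tested, 8351 passed both comparisons with LUC in the same direction, 4144 higher and 4207 lower, and 302 in opposite directions. Independent lists of these sizes would share 3444, and simulated unchanged groups against 1 set of simulated LUC libraries shared 0.2 on average and 1 at most in 20 runs. The covariance of the fold changes across genes was 1.57, against 0.0187 in the simulations, with r of 0.901 against 0.486. Both comparisons use the same 3 LUC libraries, which are too few to split, so part or all of the excess may come from them. The simulations held only spread between libraries and no shift of the LUC culture, so their low count does not test this. In LNCaP, 218 genes passed both comparisons with LUC in the same direction and 195 in opposite directions, where independent lists would share 185 (simulations 0.05 on average and 1 at most; covariance 0.716 against 0.0223, r 0.395 against 0.499). That count was 695 without LNCaP CTNNB1 replicate 1, where independent lists would share 465, 137 without replicate 2 (137) and 122 without replicate 3 (101), and it was 77, 98 and 118 without LUC replicates 1, 2 and 3 (69.1, 90.2 and 108).

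RSPO2 against CTNNB1 in PC3 asks where the constructs differ without the LUC libraries as reference. Among ATF4 and amino acid stress genes, SLC7A5 was at -1.61 (SE 0.07, adjusted p = 1.55e-11), MTHFD2 at -1.33 (SE 0.06, adjusted p = 5.58e-11) and the cystine transporter SLC7A11 at -1.20 (SE 0.07). Among cell cycle genes, the methylation maintenance factor UHRF1 was at 0.82 (SE 0.09) and the replication clamp PCNA at 0.41 (SE 0.05). CPB1 was at least 114-fold higher, the vitamin B12 binder TCN1 rose by 6.33, from 0.494 ± 0.179 to 41.6 ± 2.70 CPM (SE 0.30, adjusted p = 1.34e-10), the ratio for WDR72 was 102 (95% interval 17.9 to 4072), AFF2 was at least 5.43-fold and TNS1 at least 5.07-fold higher, and the potassium channel KCNB1 rose by 4.94 (SE 0.10, adjusted p = 3.23e-15). The phosphatase subunit PPP2R2C fell by 4.68, from 17.4 ± 0.954 to 0.679 ± 0.253 CPM (SE 0.26, adjusted p = 5.85e-10), and GLB1L3 by 3.71 (SE 0.32, adjusted p = 1.3e-07). Of 16214 genes, 5592 passed the threshold, 2836 higher and 2756 lower, and 864 of them changed over 2-fold. The groups did not overlap at 46.8% of the genes, where chance gives 10%.

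ATF4 and amino acid stress genes gave 0 rises and 28 falls among 30, with a median of -0.96 (adjusted p = 2.9e-16; 0.396 with an estimated correlation, also a p). G1/S genes gave 24 rises and 0 falls among 39, or 25 and 0 adjusted over the list alone (adjusted p = 3.14e-06; 0.488 with an estimated correlation, also a p). G2/M genes gave 21 rises and 1 fall among 43, or 24 and 1 adjusted over the list alone, with CCNA2 at 0.66 (SE 0.09) and KIF20B at -1.17 (SE 0.08) (adjusted p = 2.35e-05; 0.707 with an estimated correlation, also a p). Hypoxia genes gave 2 rises and 21 falls among 34, or 2 and 23 adjusted over the list alone, with HK2 at -0.68 (SE 0.05) and VEGFA at -0.98 (SE 0.08) (adjusted p = 7.52e-06; 0.463 with an estimated correlation, also a p). Cholesterol synthesis genes gave 15 rises and 0 falls among 24, the same adjusted over the list alone, with INSIG1 at 1.19 (SE 0.09) (adjusted p = 2.35e-05; 0.396 with an estimated correlation, also a p). Unfolded protein response genes gave 2 rises and 16 falls among 25, or 2 and 18 adjusted over the list alone, with EDEM1 at -1.01 (SE 0.05) (adjusted p = 8.32e-05; 0.488 with an estimated correlation, also a p). Antioxidant genes under NRF2 gave 12 rises and 3 falls among 17, the same adjusted over the list alone, with NQO1 at 0.69 (SE 0.06) and SLC7A11 among the falls (adjusted p = 0.00793; 0.488 with an estimated correlation, also a p). Over normalization, filter, block and left-out libraries, the adjusted p of these lists stayed between 5.21e-17 and 0.0227.

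Among Wnt/β-catenin target genes 7 of 19 rose and 3 fell with RSPO2 against CTNNB1 (adjusted p = 0.222), with LGR5 at 1.74 (SE 0.07, adjusted p = 1.6e-11), AXIN2 at 1.95 (SE 0.39, adjusted p = 0.000985), CCND1 at 0.62 (SE 0.04, adjusted p = 9.38e-09) and MYC at -0.67 (SE 0.05, adjusted p = 1.91e-08). SNAI2 was higher by 3.01 (SE 0.40, adjusted p = 2.07e-05). AR was at 1.19 (adjusted p = 0.151), and it passed with no filter (1.19, adjusted p = 5.27e-06) and without PC3 CTNNB1 replicate 1 (5.12, adjusted p = 3.12e-08). With all libraries, camera called the Wnt target list in none of the 9 comparisons.

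The LUC libraries of both lines give the baseline difference between PC3 and LNCaP. Among luminal and androgen-regulated genes, KLK3 stood at a ratio of 0.000105 (95% interval 1.27e-05 to 0.000378), CDH1 at -6.55 (SE 0.21, adjusted p = 2.56e-17), the iron reductase STEAP2 at -5.10 (SE 0.07, adjusted p = 2.16e-22) and AR at -2.91 (SE 0.17, adjusted p = 1.17e-12). In the other direction, MMP14 was at 12.49 (SE 0.22), PLAU at 11.34 (SE 0.21, adjusted p = 5.87e-21), VIM at 10.84 (SE 0.47, adjusted p = 6.25e-15) and ZEB1 at 4.78 (SE 0.09, adjusted p = 9.18e-21). Among Wnt genes the ratio for LGR5 was 582 (104 to 23039), while NKD1 was at -4.95 and MYC at -1.01 (SE 0.05, adjusted p = 9.98e-15). Of 18285 genes, 15219 passed the threshold, 7711 higher and 7508 lower in PC3, with 84.0% not overlapping where chance gives 10%. PC3-type markers gave 15 rises among 15 (adjusted p = 8.45e-06; 0.232 with an estimated correlation, also a p), luminal markers 13 falls among 14 (adjusted p = 0.000147; 0.360 with an estimated correlation), and mesenchymal genes 24 rises and 2 falls among 28 (adjusted p = 6.83e-06; 0.232 with an estimated correlation). G1/S genes gave 1 rise and 38 falls among 39, with DHFR at -3.47 (SE 0.07) and MCM2 at -2.63 (SE 0.06) (adjusted p = 1.64e-10; 0.232 with an estimated correlation). These counts were the same adjusted over the list alone, and the adjusted p of these 4 lists stayed between 2.8e-11 and 0.00018 over normalization, filter, block and left-out libraries.

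The difference between the lines in the effect of CTNNB1, PC3 minus LNCaP, was tested as an interaction. Effect here means the difference from LUC within a line. A difference between PC3 cultures unrelated to the constructs would enter this test like an effect of CTNNB1, and these values cannot tell them apart. Interferon genes also rose with RSPO2 against LUC in PC3. Interferon genes had a higher effect in PC3, with STAT1 at 2.31 (SE 0.17, adjusted p = 4.12e-10) and HERC6 at 4.23 (SE 0.31), and 35 members higher and 1 lower among 44 (adjusted p = 1.28e-12; 0.298 with an estimated correlation, also a p). Cholesterol synthesis genes had a lower effect, with DHCR24 at -1.85 (SE 0.08, adjusted p = 1.28e-13) and 0 members higher and 23 lower among 24 (adjusted p = 1.85e-11; 0.145 with an estimated correlation, also a p). ATF4 genes had a higher effect, with PSAT1 at 1.88 (SE 0.09, adjusted p = 1.39e-12) and 23 members higher and 1 lower among 30, or 24 and 1 adjusted over the list alone (adjusted p = 1.3e-08; 0.249 with an estimated correlation, also a p). MYB differed by 9.99 (SE 0.32, adjusted p = 1.52e-15) and AXIN2 by -3.83 (SE 0.45, adjusted p = 4.76e-07). Of 18285 genes, 8099 passed, 3816 higher and 4283 lower, and these list p-values stayed between 5.7e-16 and 4.09e-08 over normalization, filter, block and left-out libraries. Counts of the interferon and cholesterol lists were the same adjusted over the list alone.

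The difference for RSPO2 rests on the libraries labelled LNCaP RSPO2 with their PC3-type profile. Genes of TGF-β signalling had a negative difference, with FST at -13.18 (SE 0.21, adjusted p = 1.23e-21) and COL4A2 at -7.16 (SE 0.13), and 1 member higher and 24 lower among 28. YAP/TAZ target genes gave 2 higher and 20 lower among 22, with IGFBP3 at -9.49 (SE 0.16, adjusted p = 2.86e-21) and CCN1 at -7.92 (SE 0.15). Both lists had an adjusted p of 1.21e-05 (0.048 with an estimated correlation, also a p) and the same counts adjusted over the list alone. Of 18285 genes, 13674 passed, 6534 higher and 7140 lower. Interferon genes gave 14 higher and 14 lower among 44 (adjusted p = 0.572).

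Across lines, the comparisons share no library. With RSPO2, 3498 genes passed in both comparisons in the same direction and 4985 in opposite directions. Independent lists would share 4078 in the same direction. The libraries labelled LNCaP RSPO2 resemble PC3 LUC, which is the group subtracted in the PC3 comparison. Opposite directions can arise from this alone, so the RSPO2 counts do not compare the effect of RSPO2 between the lines. With CTNNB1, 150 passed in the same direction and 149 in opposite directions, where independent lists would share 124 in the same direction. The count of 150 was 382 without LNCaP CTNNB1 replicate 1, where independent lists would share 332, 86 without replicate 3 (68.3), 64, 76 and 93 without LNCaP LUC replicates 1, 2 and 3 (46.9, 62.0 and 77.1), and 81 without the doubted libraries (65.7).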

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

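The tests chosen only after their result was seen were the swap with the PC3 RSPO2 libraries, the position of the libraries labelled LNCaP RSPO2 between PC3 groups, and all tests on transcripts of the other line, and so were the alternatives without doubted or mixed libraries.

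The change with each construct in PC3 minus that in the libraries labelled LNCaP was tested directly. For RSPO2 this sets a PC3-type profile against a LNCaP-type one, so it does not show that the effect of RSPO2 differs between the lines. For RSPO2, 13674 genes passed, and 1 of 50 drawn splits of the 200 possible, the real one, gave as many, with 10967 as the highest other value. That value came from splits that kept the LNCaP groups whole (5 splits, median 10850), while 8 splits that kept the PC3 groups gave at most 2185 and the 36 that kept neither gave 0, which points to the structure of the LNCaP samples, so the count mostly restates the contrast within the libraries labelled LNCaP. For CTNNB1, 8099 genes passed, and 2 of 50 drawn splits gave as many, the other with 8159. The split with 8159 kept the groups of both lines and exchanged the labels in one of them, splits that kept only the PC3 groups gave up to 7792, and those that kept only the LNCaP groups up to 7, which points to the structure of the PC3 samples, so the count mostly restates PC3 CTNNB1 against LUC. These splits therefore do not test chance for a difference between the lines.

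For RSPO2, with the same limit, the difference in log2 fold change was 0.48 for CTNNB1 (SE 0.06, adjusted p = 8.83e-07), -14.42 for PLAU (SE 0.23, adjusted p = 1.24e-21), -2.07 for AXIN2 (SE 0.39, adjusted p = 6.22e-05), 1.56 for ZNRF3 (SE 0.14, adjusted p = 3.2e-09), -5.07 for TCF7 (SE 0.32, adjusted p = 7.21e-12) and -1.36 for CCND1 (SE 0.10, adjusted p = 9.83e-11). It was 2.64 for AR (SE 0.51, adjusted p = 8.09e-05), 4.25 for TMPRSS2 (SE 0.28, adjusted p = 1.26e-11), 5.34 for CDH1 (SE 0.54, adjusted p = 1.46e-08), -10.23 for VIM (SE 0.56, adjusted p = 4.9e-13), -4.91 for ZEB1 (SE 0.11, adjusted p = 2.67e-19), -3.55 for SNAI2 (SE 0.30, adjusted p = 7.86e-10) and 0.85 for MKI67 (SE 0.14, adjusted p = 1.03e-05). The TGF-β response list had a median difference of -2.92, or -2.9 recomputed from pooled group counts with groups of 0 reads set to the floor. Of its 28 members, 4 had a group at or under the floor. The YAP/TAZ target list had a median of -4.24, or -4.27 recomputed in the same way, with 2 of its 22 members having a group at or under the floor. These 2 lists passed camera with an estimated correlation (adjusted p = 0.048 each), and over normalization, filter, block and left-out libraries the adjusted p at the preset correlation stayed between 9.35e-06 and 1.39e-05.

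For CTNNB1 the difference was -0.22 for CTNNB1 itself (SE 0.06, adjusted p = 0.00848), which lost its call with no filter (-0.20, adjusted p = 0.149), 9.99 for MYB (SE 0.32, adjusted p = 1.52e-15), -10.12 for MUC5B (SE 2.25, adjusted p = 0.000914), -3.83 for AXIN2 (SE 0.45, adjusted p = 4.76e-07), 0.72 for MYC (SE 0.06, adjusted p = 7.48e-09) and -0.73 for CCND1 (SE 0.10, adjusted p = 5.48e-06). It was -5.18 for AR (SE 0.38, adjusted p = 4.94e-10), which was -9.12 without PC3 CTNNB1 replicate 1 (adjusted p = 2.59e-15), -1.02 for TMPRSS2 (SE 0.26, adjusted p = 0.00297), -4.08 for VIM (SE 0.77, adjusted p = 0.000177), which was -2.44 without LNCaP CTNNB1 replicate 2 (adjusted p = 1.05e-05), -0.74 for ZEB1 (SE 0.16, adjusted p = 0.00101) and -6.34 for SNAI2 (SE 0.39, adjusted p = 4.1e-11). For MKI67 it was 0.41 (SE 0.14, adjusted p = 0.018), and that call ended without LNCaP LUC replicate 2 (0.0638) and without PC3 CTNNB1 replicate 2 (0.112).

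The libraries labelled LNCaP RSPO2 showed a PC3-type profile: 76 genes typical of LNCaP LUC stood at a median of 0.326% of their LNCaP LUC level, 14 luminal markers at 1.64%, and 260 genes typical of PC3 LUC at 72.9% of their PC3 LUC level. An RSPO2 effect on LNCaP cells would have to silence genes that LNCaP keeps and restore MSH2, which it has lost, and CTNNA1 was at most 0.590% of the LNCaP LUC level against a bound of 5% set for such an effect, although the slope of the fold changes on those of PC3 RSPO2 against CTNNB1, 0.616 across 15423 genes, had the size such an effect predicted. A swap with the PC3 RSPO2 libraries is argued against, since LNCaP-type genes stood at a median of 0.175% of the LNCaP LUC level in those. The values are consistent with PC3-type cells in place of LNCaP cells, with CTNNA1 at 0.394% to 0.590% of the LNCaP LUC level (PC3 groups 0.376% to 1.09% on average), MSH2 at 1.29 times the mean of the PC3 groups, and PTEN not decisive at 0% to 35.1% of the LNCaP LUC level. Which step put them there stays open, as does any part that RSPO2 plays in these libraries.

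In PC3 the RSPO2 and CTNNB1 libraries differed from LUC in the same direction at 8351 genes. Depth of the LUC libraries is argued against, since 8014 such genes (96.0%) remained in number after thinning all PC3 libraries to 8951320 reads. The libraries labelled LNCaP RSPO2 held 0.404 of the RSPO2 level of PC3 RSPO2, as a ratio of mean CPM. On log2 CPM they lay at a median position of 0.415 between PC3 LUC (0) and PC3 RSPO2 (1), from 0.401 to 0.433 per library with quartiles of 0.0534 and 0.780, and at 0.367 over the 2498 genes changed over 2-fold. The share and the position are on unlike scales, so their closeness is no match of effect to RSPO2 level. A LUC culture that stands apart and an effect shared by both constructs cannot be told apart by these values, since an effect in proportion to RSPO2 also predicts a middle position. The bounds were reset after 0.415 was seen (those first written would have favored the culture). For the 42 interferon genes among the 8351 the position was 0.0833, from 0.0225 to 0.176 per library, near the PC3 LUC end. This argues against a shared effect in proportion to the RSPO2 level at these genes, with a bound added after the value was seen that sets the log2 position against the CPM share. An effect that needs the higher RSPO2 level, or one of CTNNB1 alone, is not tested by these libraries. A difference between the cultures that is unrelated to the constructs stays open.

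LNCaP CTNNB1 replicate 2 held transcripts of 54 PC3-type genes, a median of 23 reads against 1 and 2 in replicates 1 and 3, and PC3 CTNNB1 replicate 1 held transcripts of 34 LNCaP-type genes, 13 reads against 1 and 0; these genes had at most 3 reads in the LUC libraries of the line together and at least 50 CPM in CTNNB1 libraries of the other line, and levels in the other CTNNB1 libraries of the line played no part in choosing them. CTNNB1 acting on these cells is argued against, since at least 91.2% of such genes had more reads in that library than in both others of its group (100% in LNCaP), although these 2 libraries were picked for such reads, by a test that replaced an undecided one (29.6% and 26.5% of genes higher in every CTNNB1 than in every LUC library). Index bleed into LNCaP CTNNB1 replicate 2 from pooled PC3-type libraries is argued against by 2 RSPO2 reads, with 107 predicted (lower limit 91). The pool left out PC3 CTNNB1 replicate 1, and bleed from single libraries was not tested. The values are consistent with RNA or cells of the other line: across genes the levels followed those of the other line's CTNNB1 libraries with a Spearman rho of 0.914 in LNCaP CTNNB1 replicate 2 and 0.656 in PC3 CTNNB1 replicate 1, and the summed level was 1.78% of PC3 CTNNB1 (0.0675% and 0.196% in the other 2) and 2.56% of LNCaP CTNNB1 (1.23% and 1.26%). For LNCaP CTNNB1 replicate 2 the rho was 0.638 with PC3 RSPO2, 0.212 with PC3 LUC and 0.196 with the libraries labelled LNCaP RSPO2. The low rho across these 54 genes argues against PC3 LUC and the libraries labelled LNCaP RSPO2 as its main source. RSPO2 itself had 2 reads in it, against 9959 to 10997 in PC3 RSPO2, which on 1 gene argues against that group. The genes were chosen by their level in CTNNB1 libraries, so the rho alone does not name the source. For PC3 CTNNB1 replicate 1 the rho was 0.672 with LNCaP LUC, above the 0.656 with LNCaP CTNNB1, and which group its material came from stays open.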

How the results depend on the processing

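The alternatives chosen only after the data were seen were those without doubted or mixed libraries. Of the 9 comparisons, 8 kept their number of calls within 1.5 times under every alternative. CTNNB1 against LUC in LNCaP, with 451 calls, gave 1153 with no filter (35300 genes tested), 283 with the replicate number as a block, 781 with all 18 libraries in one fit (62.5% higher against 44.3%), 265 without the doubted libraries, and 175 (without LUC replicate 1) to 1120 (without CTNNB1 replicate 1) on leaving out 1 library. The genes shared in LNCaP (218) were 673 with no filter, 129 with the block, and 77 to 695 on leaving out 1 library. The CTNNB1 genes shared across lines (150) were 425 with no filter, 81 without the doubted libraries, and 64 to 382 on leaving out 1 library. The cause was not tested. Replicate numbers share only a number: deviations of libraries with the same number correlated at -0.0878 to 0.0433, and 1 of 9 LNCaP and 4 of 9 PC3 libraries correlated best with their own number. The block moved no other count of calls by over 1.5 times, ended 5 of 302 results of named genes and 2 list calls, and added 4 list calls.

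Lists that turned direction were neuroendocrine genes in LNCaP RSPO2 against LUC (fry adjusted p = 2.37e-05, down), Wnt targets in PC3 RSPO2 against LUC (fry 0.00091, up), fibroblast markers in PC3 RSPO2 (fry 0.0207, down) and PC3 CTNNB1 against LUC (fry 0.0113, down), and PC3-type markers in LNCaP CTNNB1 against LUC without the doubted libraries (0.833, down); the cause was not tested. An estimated correlation ended 132 of 134 list calls. Of 273 list results, fry ended 14 calls and added 76. Of named gene results, leaving out 1 library ended 78 and added 17 of 2232, DESeq2 ended 6 and added 3 of 297 (5 had no adjusted p), and no filter ended 4 and added 7 of 302. No normalization moved the median of all genes by over 0.1. Depth limits genes under about 0.335 CPM, the floor of the smallest library.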

Other observations

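The tests chosen only after the result was seen were the comparisons of the libraries labelled LNCaP RSPO2 with the PC3 groups.

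Members of other gene lists also changed in PC3, while the NF-κB, p53, neuroendocrine and mitochondrially encoded lists did not pass as lists with all libraries. Inflammatory genes of the NF-κB list went both ways against LUC, with 8 rises and 12 falls among 24 with RSPO2 (adjusted p = 0.42) and 6 and 11 with CTNNB1 (adjusted p = 0.105); the cytokine IL1B fell by 5.48 with RSPO2 (SE 0.13, adjusted p = 3.02e-15) and by 7.03 with CTNNB1 (SE 0.16, adjusted p = 9.18e-16), and the chemokine CXCL8 was at -3.80 (SE 0.19) and -2.75 (SE 0.17). Immediate early genes gave 5 rises and 14 falls among 25 with RSPO2, with PHLDA1 at -1.67 (SE 0.05, adjusted p = 1.83e-14), JUN at -1.42 (SE 0.06) and KLF10 at 1.16 (SE 0.05) (list adjusted p = 0.0296, 0.0144 to 0.0504 over the alternatives and highest without LUC replicate 2; 0.497 with an estimated correlation, also a p). Replication-dependent histone genes gave 8 rises and 1 fall among 13 with each construct, with H4C8 at 1.32 (SE 0.12, adjusted p = 4.36e-08) with RSPO2 and 1.54 (SE 0.12, adjusted p = 4.44e-09) with CTNNB1; the list's adjusted p was 0.0472 with RSPO2, between 0.0158 and 0.0794 over the alternatives and highest without RSPO2 replicate 3, and 0.0294 with CTNNB1, between 0.0066 and 0.0345 (0.492 and 0.471 with an estimated correlation, also p). Histone transcripts without a poly(A) tail depend on the library type. Of 26 p53 target genes, 9 rose and 12 fell with RSPO2, or 10 and 13 adjusted over the list alone (adjusted p = 0.368), with the cell cycle inhibitor CDKN1A at -2.29 (SE 0.09, adjusted p = 2.36e-12). Fatty acid synthesis genes gave 3 rises and 9 falls among 16 with CTNNB1, with ACLY at -1.02 (SE 0.05, adjusted p = 7.07e-12) and SCD at -0.99 (SE 0.05) (list adjusted p = 0.0426, 0.0319 to 0.059 over the alternatives and highest without CTNNB1 replicate 3; 0.264 with an estimated correlation, also a p). Among 9 neuroendocrine genes 2 rose and 6 fell with RSPO2, with ENO2 at -1.30 (SE 0.07) and SYP at 2.93 (SE 0.39) (adjusted p = 0.208). Mitochondrially encoded genes gave 0 rises and 6 falls among 13 with CTNNB1, or 0 and 4 adjusted over the list alone, with MT-ND3 at -0.83 (SE 0.17, adjusted p = 0.000534) (list adjusted p = 0.142, 0.0145 to 0.315 over the alternatives; 0.724 with an estimated correlation, also a p). Without PC3 CTNNB1 replicate 1, which holds transcripts of the other line, 0 of the 13 rose and 12 fell, and the list was called (0.0145). Unless another count is given, these counts were the same adjusted over the list alone, except 6 and 12 for the NF-κB list with CTNNB1.

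Set against PC3 LUC instead of LNCaP LUC, the libraries labelled LNCaP RSPO2 gave 8495 calls among 18285 genes, 4188 higher and 4307 lower, with 1981 over 2-fold, against 9446 with PC3 RSPO2 and 10172 with PC3 CTNNB1 as the reference. Cell cycle genes were higher than in PC3 LUC, with 38 rises and 2 falls among 43 G2/M genes (adjusted p = 1.33e-11; 0.48 with an estimated correlation, also a p) and 33 and 1 among 39 G1/S genes (adjusted p = 1.37e-10; 0.426 with an estimated correlation, also a p). Cholesterol synthesis genes were lower, with 0 rises and 21 falls among 24 (adjusted p = 5.84e-10; 0.238 with an estimated correlation, also a p), and so were unfolded protein response genes, with 0 and 22 among 25 (adjusted p = 1.31e-07; 0.48 with an estimated correlation, also a p). Interferon genes gave 9 rises and 6 falls among 44 (adjusted p = 0.493), and Wnt target genes 9 and 8 among 27 (adjusted p = 0.717). Counts adjusted over the list alone were not computed for these lists.

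An RSPO2 effect common to both sets of PC3-type libraries was a hypothesis that predicted like fold changes of the libraries labelled LNCaP RSPO2 against PC3 LUC and of PC3 RSPO2 against PC3 CTNNB1. The Spearman rho across 18284 genes was 0.0494, under the bound of 0.1 set against such an effect, while 1847 genes were called in the same direction, over 1.5 times the 1225 of independent lists, as such an effect predicted, and 1390 in opposite directions. Since PC3 RSPO2 against PC3 CTNNB1 cancels whatever both constructs share, these values do not exclude such an effect, and it stays open.

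For the 7 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real number of calls and the highest of the other splits were 14262 and 0 for the libraries labelled LNCaP RSPO2 against LUC, 451 and 2 for LNCaP CTNNB1 against LUC, 14276 and 0 for the libraries labelled LNCaP RSPO2 against LNCaP CTNNB1, 10504 and 1 for PC3 RSPO2 against LUC, 10634 and 0 for PC3 CTNNB1 against LUC, 5592 and 0 for PC3 RSPO2 against CTNNB1, and 15219 and 0 for the LUC libraries of both lines; the real split alone (1 of 10) gave as many each time. Libraries of a group differed beyond sampling noise, with a chi-square per degree of freedom of 2.11 to 9.32.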
